A study of Melitaea cinxia with 170 samples.

How the data were processed

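The series measured gene expression in the thorax of the Glanville fritillary butterfly (Melitaea cinxia) by RNA sequencing. The thorax is the body segment that carries the wings and holds the flight muscles. The 85 butterflies came from populations of separate Baltic islands, named AL (Åland) and PT (Pikku Tytärsaari) in the labels. Each butterfly was either put through a flight treatment or handled as a control without it, and was frozen 1 h or about 20 h after the start. The labels give population, sex and treatment for every butterfly, which makes 16 groups of 2 to 10 butterflies.

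Per the labels' protocols, total RNA was extracted from the frozen thorax, and strand-specific libraries were built by an in-house method anchored at the polyA tail, with average inserts of 450 nt and 650 nt for each butterfly. Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.5 and edgeR were used, with no role or order given. The genome build, the annotation, the counting tool and whether counting used strand are not given in the sources used here. Reads from overlapping genes or near-identical copies could therefore be split in ways that the counts do not show.

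The authors deposited whole-number read counts per gene model for each of the 170 libraries, with no normalization, for 16667 gene models, of which 15763 had at least 1 read. The authors also deposited a normalized table of 8258 genes for the 85 butterflies, treated here as a signal of unnamed scale. In 100% of its values it equalled the summed counts of both libraries times 1 factor per butterfly, to within 0.0006 plus 1e-06 of the value. Its column sums ran from 525595 to 1475037. It served as a check that the libraries of each butterfly were paired as the authors paired them, and its gene list was an alternative filter.

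Totals per library ran from 659410 to 4349250 counts (median 1949153), and totals per butterfly from 1820059 to 6944328 (median 3955268). Counts were concentrated: the 10 most abundant genes held 27.3% of all counts, and 46 genes held 50%. No libraries had identical counts. Libraries were compared after subtracting the mean of each insert size over the 4853 genes with a mean of at least 5 CPM (read counts relative to the scaled library total). All 170 libraries then correlated best, across genes, with the other library of the same butterfly. Without that subtraction, and over all tested genes, 140 did, and 25 of the other 30 were closest to a library of the same insert size. Genes are not independent replicates, so these correlations only describe the pairing.

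The replicate is the butterfly. Counts of its libraries were summed, and the labels make the butterflies separate individuals, so p-values cover the spread between butterflies. The model, tests, alternatives and rule for named genes were fixed before the data were examined. Genes were filtered with filterByExpr over the 4 treatments, which left 7643 genes holding 99.76% of the counts. Factors from TMM scaling ran from 0.66 to 1.9. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit) on all 85 butterflies, with the means of the 8 population by treatment cells and sex as an additive term. Sex differences in the flight effect used the 8 sex by treatment cells with population as the additive term. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.68. Libraries of different insert size were compared by limma 3.58.1 on within-butterfly differences of log2 CPM with a prior count of 2.

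Named genes had to pass the test, average at least 5 CPM, and change in the same direction in both populations, or in both sexes for population comparisons. The largest rises and falls were taken. Gene models carry project identifiers, and 0 of the 16667 identifiers matched the reference table of gene names (assembly ilMelCinx1.1), so no name, function or position is given for any gene, and at most 2 identifiers that rose and 2 that fell are named per comparison. The gene lists fixed in advance, which covered energy metabolism, muscle, stress, immunity and markers of other tissues, were not analysed here, because they need names or sequences for these identifiers. Cell-type markers were not checked for the same reason.

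The procedure was tested on simulated counts drawn from the means and library sizes of the 7643 genes, with 100 genes changed 2-fold and 100 changed 4-fold per comparison. Flight at 1 h recovered 36% of 2-fold and 88% of 4-fold changes, and flight at 20 h 52% and 84%. The contrast of controls recovered 33% and 75%. The difference between flight effects at 20 h and 1 h recovered 22% and 61%. Population recovered 60% and 96%, and sex 62% and 97%. The population difference in the flight effect recovered 3% and 38% at 1 h and 3% and 37% at 20 h. The sex difference in the flight effect recovered 17% and 62%. Wrong calls made up at most 8.5% of the calls in any comparison.

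Alternatives were DESeq2 size factors, no count filter, the genes of the authors' table, the DESeq2 1.42.0 Wald test, limma voom with quality weights, each insert size alone, 16 cells with equal weight, 2 surrogate variables (sva 3.50.0), females alone, each population alone, and leaving out each butterfly of the groups of 2 to 5. Thinning every butterfly to the total of the shallowest, and excluding the 100 most abundant genes, were added after seeing the data. For each comparison, group labels were also permuted within strata of the other factors in 99 random splits, refitting the model each time. Single values were compared with 2-sided permutation tests in scipy 1.17.1, exact where a group had under 10 butterflies and with 100000 resamples otherwise. Figures were drawn with matplotlib 3.10.9.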

Results

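Thorax transcriptomes were obtained from 85 Glanville fritillary butterflies, 40 from AL and 45 from PT, of which 53 were females and 32 were males. At 1 h, 29 flown butterflies were compared with 13 controls, and at 20 h, 30 flown butterflies with 13 controls. Each butterfly gave 2 libraries, whose counts were summed to between 1820059 and 6944328 per butterfly. Male totals averaged 4782166 ± 1159478 counts (SD, n = 32) and female totals 3636567 ± 1047135 (n = 53), and the means differed (permutation test, 2-sided, p = 4e-05, adjusted p = 0.00016 over 12 comparisons). The 10 most abundant genes took 29.5% ± 2.7 of the counts in males and 25.1% ± 5.07 in females (permutation p = 2e-05, the smallest the resamples can give, adjusted p = 0.00012). Their share was also lower in flown butterflies at 1 h, at 26.7% ± 4.71 (n = 29) against 30.3% ± 3.03 in controls (n = 13; permutation p = 0.011, adjusted p = 0.033). At 20 h the shares were 24.8% ± 4.81 in flown butterflies and 28% ± 4.44 in controls, and the difference missed the threshold after adjustment (permutation p = 0.045, adjusted p = 0.11). All genes are given by their identifiers, since none could be paired with a name.

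Population and sex set the main axes of variation. The first principal component of log2 CPM over 7643 genes held 14.3% of the variance, and population accounted for a fraction of 0.98 of its scores. The second component held 5.2% of the variance, and sex accounted for a fraction of 0.568 of its scores. Treatment accounted for fractions of 0 and 0.087 of the scores on these components, and for 0.294 and 0.307 on the third and the fourth, which held 4.1% and 3.3% of the variance.

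**Figure D1:**
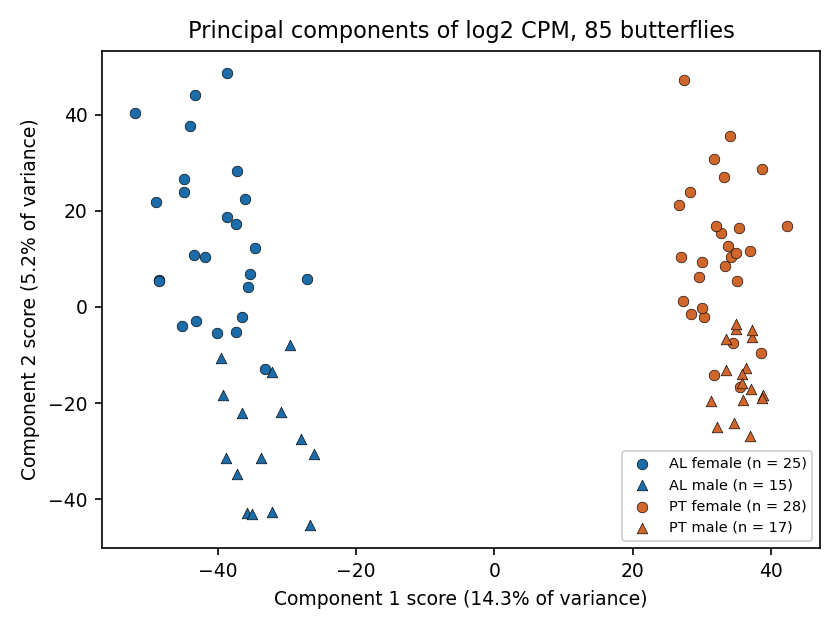
Scores of the 85 butterflies on principal components 1 (horizontal axis, 14.3% of variance) and 2 (vertical axis, 5.2% of variance) of log2 CPM; each point is a butterfly, colour gives the population and shape the sex. AL and PT butterflies lie on opposite sides of component 1 with no overlap, and males lie mostly lower than females on component 2.

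The contrast of flown and control butterflies at 1 h asked which genes respond soon after flight. MCINXTMP_003386 showed the largest rise, from 6.51 ± 10.1 CPM in controls (SD, n = 13) to 55.6 ± 35.6 CPM in flown butterflies (n = 29), a log2 fold change of 3.67 ± 0.66 (SE; edgeR adjusted p = 0.000874). MCINXTMP_009203 rose from 24.6 ± 25 to 232 ± 168 CPM, a log2 fold change of 3.28 ± 0.56 (edgeR adjusted p = 0.000333). MCINXTMP_011856 fell from 11.5 ± 8.39 to 3.71 ± 3.06 CPM, with a log2 fold change of -1.59 ± 0.39 (edgeR adjusted p = 0.0361). MCINXTMP_011855, the gene model numbered next to it, fell from 19.4 ± 10.9 to 8.07 ± 6.55 CPM, with a log2 fold change of -1.43 ± 0.33 (edgeR adjusted p = 0.0208). In all, 25 of 7643 genes were called, 20 higher and 5 lower after flight, and 21 of them changed more than 2-fold. All 25 had the same direction in AL and PT, but genes were called on the mean of both effects, which itself favours the same direction. DESeq2 with its own scaling and filtering called 63 genes, and limma voom with quality weights 59. Females alone gave 26 genes by edgeR (25 higher, 1 lower), which held only 12 of the 25. All 25 kept their direction in these females, who are part of the main test. AL alone gave 11 genes and PT alone 0 by edgeR (362 genes at an unadjusted p under 0.05), where MCINXTMP_003386 had a log2 fold change of 2.04 (edgeR adjusted p = 0.96), and leaving out AL female control butterfly 2 or PT male control butterfly 2 gave 9 or 45. Flown PT butterflies ran from 0.594 to 134 CPM for MCINXTMP_003386, and the sources used here do not give how long each butterfly flew.

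At 20 h, the contrast asked which genes differed on the morning after flight. MCINXTMP_011164 rose from 1.14 ± 1.5 CPM in controls (SD, n = 13) to 19.7 ± 43.9 CPM in flown butterflies (n = 30), a log2 fold change of 3.82 ± 0.86 (SE; edgeR adjusted p = 0.00882). MCINXTMP_000474 rose from 32.6 ± 23.6 to 413 ± 922 CPM, a log2 fold change of 3.55 ± 0.84 (edgeR adjusted p = 0.0127). For both genes the SD among flown butterflies exceeded their mean, and single butterflies reached 221 and 4900 CPM. MCINXTMP_008074 fell from 109 ± 149 to 28.9 ± 40.7 CPM, with a log2 fold change of -2.25 ± 0.56 (edgeR adjusted p = 0.0179). This fall was uneven, at -0.79 in AL and -3.7 in PT, where control values at 20 h ran from 4.83 to 449 CPM with a median of 7.92 (n = 7). MCINXTMP_008786 fell from 25.5 ± 35.1 to 5.58 ± 7.45 CPM, with a log2 fold change of -1.74 ± 0.44 (edgeR adjusted p = 0.0189). Its fall was also uneven, at -2.81 in AL and -0.66 in PT. The test called 131 genes, 83 higher and 48 lower after flight. Of these, 63 changed more than 2-fold. All 131 had the same direction in both populations, which calling genes on the mean of both effects itself favours. DESeq2 called 297 genes and limma voom 241, equal weighting of the 16 cells left 64, and AL alone and PT alone gave 34 (22 higher, 12 lower) and 35 (15 higher, 20 lower). Of the 131 genes, 19 were called in AL alone and 13 in PT alone. Females alone gave 142 genes (99 higher, 43 lower), which held only 63 of the 131. Without the count filter there were 149 (77 higher, 72 lower), which held 98. All 131 kept their direction in both of these runs, which use butterflies of the main test. Leaving out PT female control butterfly 4 at 20 h left 66 genes, and leaving out AL female control butterfly 3 at 20 h left 82.

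**Figure D2:**
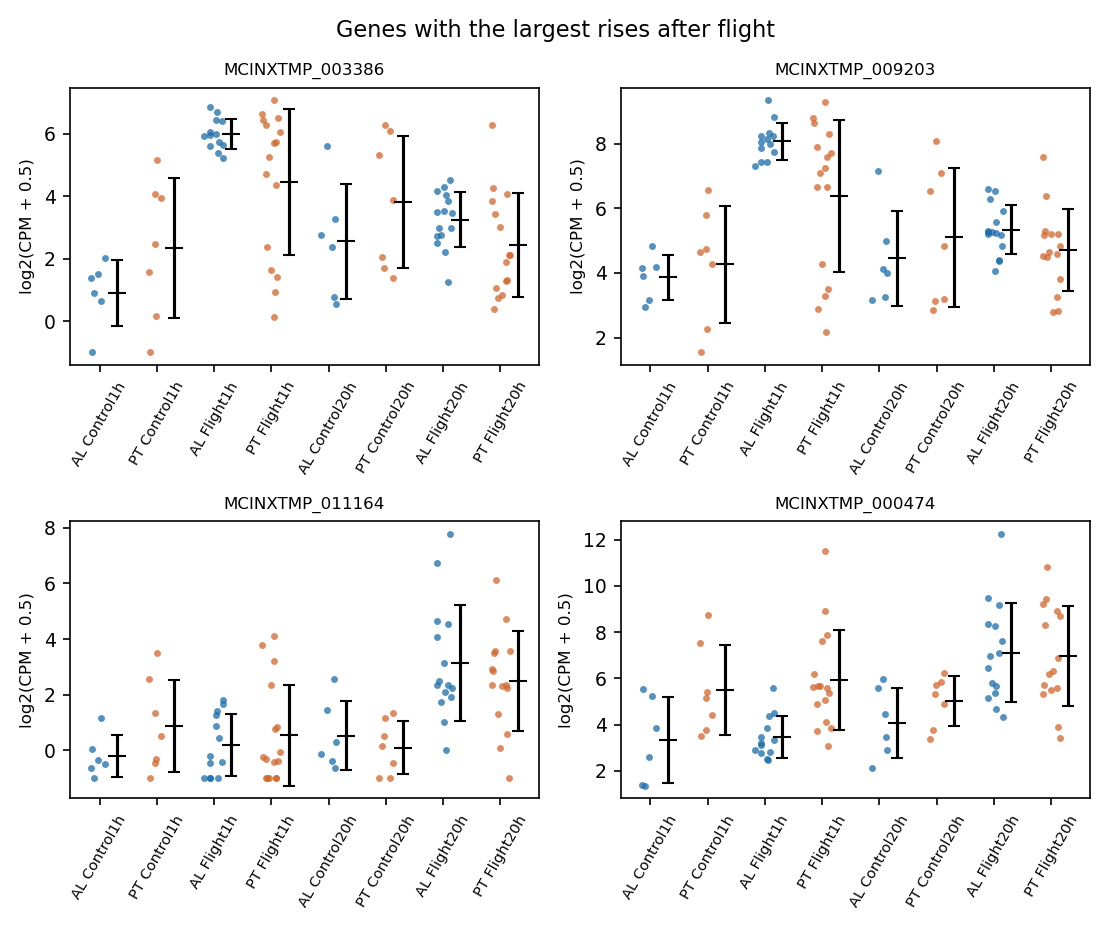
Expression of the 4 genes with the largest rises after flight, in log2(CPM + 0.5) on the vertical axis, by population and treatment on the horizontal axis. Each point is a butterfly, and bars give the mean ± SD. MCINXTMP_003386 and MCINXTMP_009203 have higher means in flown butterflies at 1 h, where MCINXTMP_003386 runs from 36.4 to 114 CPM in AL and from 0.594 to 134 CPM in PT, and MCINXTMP_011164 and MCINXTMP_000474 have higher means in flown butterflies at 20 h.

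The genes called at 1 h and at 20 h did not overlap (0 shared between the 20 higher at 1 h and the 83 higher at 20 h, where independent lists would share 0.22). Whether the effect itself differed was tested as the flight effect at 20 h minus that at 1 h, which called 50 genes, 30 higher and 20 lower. MCINXTMP_003386 had the largest fall in effect, with a log2 difference of -4.46 ± 0.81 (SE, edgeR adjusted p = 0.00122). The rise it showed at 1 h was absent at 20 h. Its level was then 10.7 ± 13.9 CPM in flown butterflies (n = 30) and 21.2 ± 26.9 in controls (n = 13), with medians of 7.34 and 6.17 CPM. MCINXTMP_009203 followed, with -3.54 ± 0.69 (edgeR adjusted p = 0.0024). MCINXTMP_008356 gained, with a log2 difference of 2.28 ± 0.56 (edgeR adjusted p = 0.0238), at 1.34 in AL and 3.22 in PT. It stood at 14.3 ± 9.64 CPM in flown butterflies at 20 h against 4.37 ± 3.88 at 1 h. MCINXTMP_015257 gained by 2.28 ± 0.58 (edgeR adjusted p = 0.0353), at 50.6 ± 47.1 CPM against 15.6 ± 17. For both of these genes the CPM are of flown butterflies only, whereas the log2 difference also takes in the controls. The count was 8 in females alone (1 higher, 7 lower), 10 in AL alone (2 higher, 8 lower) and 0 in PT alone (edgeR; 623 genes at an unadjusted p under 0.05), 24 without PT female control butterfly 4 at 1 h, and 30 without AL male control butterfly 1 at 1 h.

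Controls at 20 h and at 1 h were compared to see what an overnight stay does without flight. No gene was called by edgeR. At an unadjusted p under 0.05 there were 310 genes where chance alone gives 382, and DESeq2 called 1 gene and limma voom 0. With 13 butterflies per side, the simulated 2-fold changes were recovered in 33% of genes, so changes of that size in single genes would often go undetected.

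AL and PT butterflies differed in 3356 of the 7643 genes, 1831 higher and 1525 lower in AL. MCINXTMP_006156 stood at 105 ± 115 CPM in AL (SD, n = 40) and 1.24 ± 1.7 in PT (n = 45), a log2 fold change of 6.3 ± 0.48 (SE; edgeR adjusted p = 3.12e-19). MCINXTMP_010010 stood at 129 ± 213 CPM in AL and 2.09 ± 3 in PT, a log2 fold change of 6.22 ± 0.71 (edgeR adjusted p = 1.22e-11). In the other direction, MCINXTMP_003926 stood at 0.413 ± 0.478 CPM in AL and 75.3 ± 69.7 in PT (log2 fold change -7.34 ± 0.55, edgeR adjusted p = 1.75e-19). MCINXTMP_010661 stood at 1.55 ± 2.28 CPM in AL and 151 ± 145 in PT (log2 fold change -6.94 ± 0.48, edgeR adjusted p = 4.27e-21). Differences above 2-fold were found in 1612 genes, 1089 higher in AL and 523 higher in PT. Of the 1744 smaller differences, 742 were higher in AL and 1002 higher in PT. With DESeq2 size factors there were 1633 differences above 2-fold, 1153 higher in AL and 480 higher in PT. The 1680 smaller differences were then 806 higher in AL and 874 higher in PT, so their balance shifted with the scaling. Of the 3356 genes, 3284 had the same direction in females and males, which calling genes on both sexes together itself favours. Any batch that followed population cannot be told apart from it, as the labels give none.

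Whether flight acted alike in the populations was tested as a difference of effects. At 1 h, no gene was called by edgeR, DESeq2 or limma voom, with 369 genes at an unadjusted p under 0.05 where chance gives 382. In simulated counts this contrast recovered 3% of 2-fold and 38% of 4-fold differences, so the absence of calls does not show equal effects. Log2 effects in AL and PT were 5.21 and 2.12 for MCINXTMP_003386, and 4.29 and 2.28 for MCINXTMP_009203. They were -2.04 and -1.14 for MCINXTMP_011856, and -2.09 and -0.77 for MCINXTMP_011855. At 20 h, 6 genes were called, 4 with a higher signed log2 effect in AL than in PT and 2 with a lower one. A higher signed effect can come from a rise in AL or from a fall in PT. MCINXTMP_016298 went from 39.2 ± 20.1 CPM in AL controls (SD, n = 6) to 140 ± 97.8 in flown AL butterflies (n = 15), and from 78.2 ± 36.5 in PT controls (n = 7) to 52.9 ± 24.3 in flown PT butterflies (n = 15), a log2 difference of effects of 2.39 ± 0.54 (SE; edgeR adjusted p = 0.0477). MCINXTMP_011213 had a log2 difference of 4.75 ± 1.06 (edgeR adjusted p = 0.0477), with 19.8 ± 24.4 CPM in PT controls (n = 7) and 1.74 ± 1.82 in flown PT butterflies (n = 15). MCINXTMP_013508, an abundant transcript, went from 24800 ± 17800 to 12200 ± 7400 CPM in AL and from 13600 ± 10400 to 25500 ± 10900 in PT (log2 difference -1.93 ± 0.44, edgeR adjusted p = 0.0477). MCINXTMP_001487 went from 452 ± 224 to 238 ± 131 CPM in AL and from 227 ± 107 to 426 ± 186 in PT (log2 difference -1.72 ± 0.4, edgeR adjusted p = 0.048). The 6 calls stood close to the threshold. By edgeR none was left with equal weighting of the cells, 2 surrogate variables or females alone. These runs had 781, 627 and 736 genes at an unadjusted p under 0.05. DESeq2 called 48 (signed effect higher in AL for 17 and lower for 31) and limma voom 50 (14 and 36). The 650 nt libraries alone gave 7 by edgeR (1 and 6), so the balance of directions is not settled. Leaving out PT male control butterfly 1 at 20 h gave 26. Leaving out AL female control 3, AL male control 1, AL male control 2 or PT female control 1 at 20 h each gave 0 by edgeR (789, 730, 773 and 810 genes at an unadjusted p under 0.05). Across genes, the flight effects estimated separately in AL and PT correlated with Pearson's r = 0.12 and Spearman's rho = 0.11 at 1 h, and with 0.09 and 0.07 at 20 h. Genes are not independent replicates, and noise in both estimates lowers these values.

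Males and females differed in 1491 genes, 710 higher in males and 781 higher in females. MCINXTMP_015668 stood at 212 ± 53.8 CPM in males (SD, n = 32) and 31.6 ± 11.1 in females (n = 53), a log2 fold change of 2.76 ± 0.09 (SE; edgeR adjusted p = 1.44e-44). The lowest male, at 107 CPM, lay above the highest female, at 59.9 CPM. MCINXTMP_008527 stood at 732 ± 812 CPM in males and 144 ± 198 in females, a log2 fold change of 2.58 ± 0.58 (edgeR adjusted p = 0.000451). MCINXTMP_012856 was nearly restricted to females, at 58.2 ± 49.2 CPM against 0.46 ± 0.768 in males, with no read in 17 of the 32 males (log2 fold change -7.07 ± 0.34, edgeR adjusted p = 6.12e-32). MCINXTMP_009163 stood at 125 ± 256 CPM in females and 1.23 ± 2.8 in males (log2 fold change -6.63 ± 0.53, edgeR adjusted p = 3.96e-17). Differences above 2-fold were found in 346 genes, 133 higher in males and 213 higher in females. Of the 1491 genes, 1468 had the same direction in both populations, which calling genes on both populations together itself favours. AL alone gave 948 genes (492 higher in males, 456 higher in females) and PT alone 658 (354 and 304). The balance was 626 and 922 with DESeq2 size factors and 712 and 1169 by the DESeq2 Wald test. It was 710 and 685 without the 100 most abundant genes. TMM factors averaged 0.866 in males and 1.11 in females, and which sex has more of the higher genes is not settled.

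**Figure D3:**
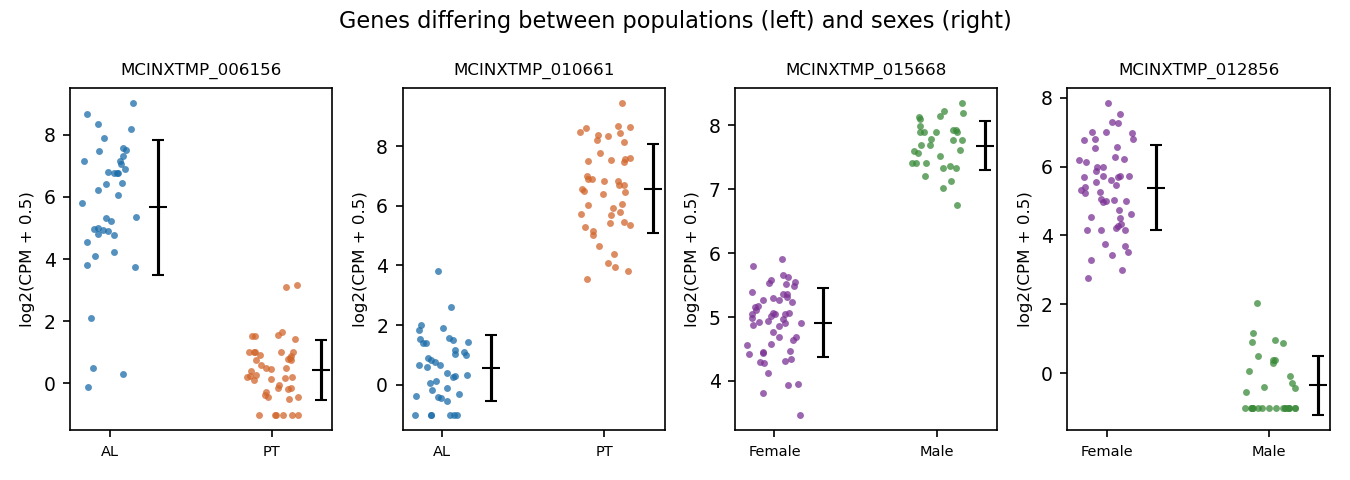
Expression in log2(CPM + 0.5), on the vertical axis, of 2 genes that differed between populations (AL, n = 40, and PT, n = 45) and 2 that differed between sexes (females, n = 53, and males, n = 32). Each point is a butterfly, and bars give the mean ± SD. For MCINXTMP_015668 the sexes do not overlap.

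The flight effect, averaged over 1 h and 20 h, differed between the sexes in 40 genes. Of these, 15 had a higher signed log2 effect in males than in females and 25 a lower one. This balance was 37 and 36 by limma voom, 59 and 76 by DESeq2, and 21 and 64 without the count filter, so it is not settled. MCINXTMP_000512 was at 457 ± 594 CPM in female controls at 1 h (SD, n = 8) and 1140 ± 777 in flown females (n = 17), whereas male controls stood at 1280 ± 648 (n = 5) and flown males at 975 ± 911 (n = 12). Its log2 difference of effects, males minus females, was -1.79 ± 0.37 (SE; edgeR adjusted p = 0.0123). MCINXTMP_009047 had a log2 difference of -2.01 ± 0.49 (edgeR adjusted p = 0.0396), with 3.25 ± 2.04 CPM in female controls (n = 9) and 10.5 ± 6.69 in flown females (n = 19) at 20 h. MCINXTMP_008282 had a log2 difference of 2.02 ± 0.5 (edgeR adjusted p = 0.0396), and fell from 60.7 ± 70 to 18.4 ± 15.2 CPM on average in the same females, while males had 23.7 ± 32.9 (n = 4) and 39.1 ± 27.4 (n = 11). MCINXTMP_005593 had a log2 difference of 2.75 ± 0.71 (edgeR adjusted p = 0.0466). Where CPM are given for these genes, they are of a single time, whereas the log2 differences average both times. Male controls numbered 5 at 1 h and 4 at 20 h, and leaving out AL male control butterfly 1 at 20 h gave 0 genes by edgeR (688 at an unadjusted p under 0.05), whereas leaving out PT female control butterfly 4 at 1 h gave 81.

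The libraries of different insert size, compared within each of the 85 butterflies, differed in 1689 genes by limma, 925 higher with 650 nt and 764 higher with 450 nt inserts. The called genes had a median absolute log2 change of 0.38, and 62 were above 2-fold (105 with a prior count of 0.5 in place of 2). Every butterfly had both sizes. For the genes over 50 CPM, a median of 72.3% of the variance within groups lay between butterflies and the rest between libraries of the same butterfly. The median was 34.2% for genes of 5 to 50 CPM and 20.3% for genes under 5 CPM.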

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

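The tests with thinned counts, the test without the 100 most abundant genes and the test of reference variants were chosen only after the result was seen, as was the count of overlaps in permuted splits, and how counting errors enter the reading of overlaps was decided, and once changed, after the overlaps were seen.

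Differences between flight effects were tested between times, populations and sexes. The difference between 20 h and 1 h called 50 genes, the population difference at 20 h called 6, and the sex difference called 40. By edgeR, the 6 became 0 with equal weighting of cells, 2 surrogate variables or females alone (781, 627 and 736 genes at an unadjusted p under 0.05), and the 40 became 0 in PT alone (418) or without AL male control 1 at 20 h (688). The named genes had log2 differences of 2.28 (MCINXTMP_008356), 2.28 (MCINXTMP_015257), -4.46 (MCINXTMP_003386) and -3.54 (MCINXTMP_009203) between times. They had 4.75 (MCINXTMP_011213), 2.39 (MCINXTMP_016298), -1.93 (MCINXTMP_013508) and -1.72 (MCINXTMP_001487) between populations at 20 h, and 2.75 (MCINXTMP_005593), 2.02 (MCINXTMP_008282), -2.01 (MCINXTMP_009047) and -1.79 (MCINXTMP_000512) between sexes. Each rests on a test of the difference itself.

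Single butterflies stood far from the rest of their group in 8 of 32 combinations of a control group with a gene named in the population or sex differences. Chance gives about 1 in 20, or 1.6, for independent combinations. These share the same control butterflies, and the genes were picked for large differences, so the chance value is only a rough guide. CPM are skewed upward, and all 8 were the highest of their group. For MCINXTMP_011213, they were 12.3 CPM among AL controls at 20 h (next 5.28) and 23 CPM among PT controls at 1 h (next 5.18). MCINXTMP_013508 reached 36600 CPM in a PT control at 20 h (next 14000), and MCINXTMP_001487 608 CPM in a PT control at 1 h (next 365). MCINXTMP_005593 reached 13.3 CPM in a male control at 1 h (next 3.19). MCINXTMP_008282 reached 227 CPM (next 92.2) and 237 CPM (next 79.9) in female controls at 1 h and 20 h, and MCINXTMP_000512 reached 1890 CPM in a female control at 1 h (next 463).

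Labels were permuted in 99 random splits, and the real split was counted as the hundredth. In 6 comparisons the real split called the most genes. As many genes as in the real split were called in 1 of 100 splits for flight at 1 h (25 genes, highest other 11), flight at 20 h (131, highest other 6), the difference between times (50, highest other 1), AL against PT (3356, highest other 109), males against females (1491, highest other 1) and the sex difference in the flight effect (40, highest other 2). For the population difference at 20 h it was 2 of 100, and the other of these splits called 14 genes against the real 6. These counts argue against chance for flight at 1 h and 20 h, AL against PT, and males against females. For the differences in flight effect between times, populations and sexes, flight and control labels were permuted, which removes flight effects altogether. Such splits cannot tell unequal from equal flight effects, so chance is not excluded for these differences by this count. For the comparison of controls (0 genes, highest other 1) and the population difference at 1 h (0 genes, highest other 6), all 100 splits called as many because no count lies below 0, so this count decides nothing there.

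The difference between AL and PT covered 43.91% of the genes tested. After every butterfly was thinned to the same total, 2769 of the 3356 called genes were still tested, and 94% of these were called. For the genes still tested, a depth difference is argued against. Reads lost at sequence variants against the reference cannot be told apart from expression. Of the calls above 2-fold, 67.6% were higher in AL, and 70.6% with DESeq2 size factors. For the smaller calls these shares were 42.5% and 48%. The scaling sets part of this balance, but most calls above 2-fold were higher in AL under both scalings. The reference's origin is not given in the sources used here, and the reads were not used. Divergence between the island populations also stays open as a hypothesis, untested here.

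The difference between males and females came with deeper libraries and more concentrated counts in males. Thinning left 1375 of the 1491 called genes tested, of which 93% were called. Excluding the 100 most abundant genes left 1428, of which 93.8% were called. Neither depth nor a few abundant genes may thus account for most calls. Another make-up of tissues in the male and female thorax was not tested, because no gene could be named as a marker, and sex itself remains an open explanation.

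Genes that fell after flight at 20 h were often genes higher in males. The lists shared 17 genes where independent lists would share 4.46. Among females alone, where sex cannot enter, the overlap was 11 against 3.97, and after thinning it was 13 against 5.05. Both met the bound of 2 times the independent value and exceeded that value itself by more than their counting errors of 3.3 and 3.6. These errors treat genes as independent, which they are not, and the male-higher list came partly from the same females. An excess thus remained without males and with equal totals, but whether it exceeds noise there was not tested. In females alone an uneven share of sexes cannot arise, and the main model also held sex as a term. At 20 h, males were 11 of 30 flown and 4 of 13 control butterflies, a balance that would raise male-higher genes after flight. These points argue against an uneven share of sexes for these genes. Total depth is not excluded, since the male-higher list came from counts that were not thinned. Error shared by the estimates of both effects stays open, as does a biological link between sex and flight, untested here. The median flight effect of the male-higher genes at 20 h was -0.1 (log2). It lay near the edge of the range of -0.12 to 0.11 of the 99 permuted splits (5 of 100 as large, the real one included). This is not particular to these genes. At 20 h the median was 0.06 for genes higher in PT (4 of 100 as large) and 0.09 for genes higher in females (7 of 100). For genes higher in AL it was -0.02 (80 of 100). Only 1 of the 18 genes called lower in the permuted splits was higher in males.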

How the results depend on the processing

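Thinning and excluding the 100 most abundant genes were chosen after seeing the data. No named gene changed direction under any alternative run. The named genes of AL against PT stayed past the threshold throughout, as did those of males against females except in 1 case. Without single butterflies, values of the named genes lost it in 10 of 124 cases at 1 h, 2 of 124 at 20 h, 11 of 124 between times, 60 of 124 for the population difference in the flight effect at 20 h and 47 of 124 for the sex difference. Under the other alternatives, these were 13 of 56, 13 of 56, 14 of 56, 27 of 47 and 22 of 52. AL against PT stayed within 1.5 times its 3356 genes under every alternative, as did males against females except in single populations (948 in AL, 658 in PT), and the insert-size difference under both of its alternatives. The population difference at 1 h stayed at 0 genes, and the comparison of controls at 0 except for 1 gene by DESeq2. Flight counts moved with other tools, which also changed scaling, filtering (2076 genes at 20 h had no adjusted p in DESeq2) or weights. DESeq2 gave 63 genes at 1 h, 297 at 20 h, 91 for the difference between times, 48 for the population difference at 20 h and 135 for the sex difference in the flight effect, and limma voom gave 59, 241, 87, 50 and 73.

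Without the count filter, 68 genes (31 higher, 37 lower) were called at 1 h, 113 for the difference between times, 3 for the population difference at 20 h and 85 for the sex difference in the flight effect. The 450 nt libraries alone gave 15 at 1 h, 62 at 20 h, 25, 1 and 9 for the same differences, and the 650 nt libraries alone gave 16 at 1 h and 26 for the difference between times; single libraries hold fewer counts. Equal weighting of 16 cells gave 64 at 20 h and 0 for the population difference at 20 h. With 2 surrogate variables there were 42 at 1 h, 0 for the population difference at 20 h and 19 for the sex difference in the flight effect. Excluding the 100 most abundant genes left 2 and 26 for these differences. With fewer butterflies, females alone gave 8 for the difference between times and 0 for the population difference at 20 h, AL alone gave 11 at 1 h, 34 at 20 h, 10 between times and 25 for the sex difference in the flight effect, and PT alone gave 0, 35, 0 and 0 (362, 623 and 418 genes at an unadjusted p under 0.05 by edgeR where it gave 0). Where an alternative reduces no genes, counts or butterflies, the cause was not tested. Similar counts can hold other genes, as in females alone. The correlation of AL and PT flight effects was 0.17 at 1 h and 0.15 at 20 h over genes of at least 5 CPM, against 0.12 and 0.09.

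Leaving out single butterflies of the groups of 2 to 5 gave 9 to 45 genes at 1 h, 66 to 186 at 20 h, 24 to 65 for the difference between times, 0 to 0 for the comparison of controls, 3277 to 3393 for AL against PT, 0 to 0 for the population difference at 1 h, 0 to 26 at 20 h, 1400 to 1504 for males against females and 0 to 81 for the sex difference in the flight effect. At 1 h, the count moved by over 1.5 times without AL female controls 1 (12 genes) and 2 (9), AL male control 1 (16), PT female controls 1 (11) and 3 (14), and PT male controls 2 (45) and 3 (12). At 20 h it did so without AL female control 3 (82) and PT female control 4 (66), and between times without the 1 h controls AL male 1 (30) and PT female 4 (24). The population difference at 20 h moved without the 20 h controls AL female 2 (17) and 3 (0), AL males 1 (0) and 2 (0), PT females 1 (0) and 2 (3), PT males 1 (26) and 2 (3), and without AL female control 4 (2) and PT male control 3 (2) at 1 h and flown AL male 3 at 20 h (1). The sex difference in the flight effect moved without the 1 h controls AL females 1 (14) and 3 (12), AL males 1 (4) and 2 (10), PT females 1 (14), 2 (5), 3 (22) and 4 (81), and the 20 h controls AL males 1 (0) and 2 (4), PT females 2 (20), 4 (20) and 5 (21) and PT male 1 (11). The camera test of gene lists and its alternative were not run, since the identifiers carry no names. No paired analysis was possible, as replicate numbers only name butterflies. Depth limited which genes could be tested: thinning left 5983 genes past the filter in place of 7643, and moved no count of calls by over 1.5 times.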

Other observations

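The values per butterfly and the spread at 1 h, the score tests within population and sex and the tests of gene numbering were chosen only after the results were seen.

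At 1 h, all 13 flown AL butterflies exceeded the highest AL control for both genes with the largest rises: MCINXTMP_003386 ran from 36.4 to 114 CPM in flown AL butterflies against at most 3.55 CPM in AL controls, and MCINXTMP_009203 from 158 to 650 CPM against at most 28.2. Among the 16 flown PT butterflies, 7 lay below the lowest flown AL butterfly for MCINXTMP_003386 and 9 for MCINXTMP_009203. The SD of log2(CPM + 0.5) among flown butterflies was 0.49 in AL and 2.34 in PT for MCINXTMP_003386, and 0.57 and 2.34 for MCINXTMP_009203, picked because the difference was seen, so no test of it is given. On a log2 score of other genes chosen in AL butterflies alone at 1 h, with both genes left out, the 16 flown PT butterflies ran from -1.11 to 1.59 and the 7 PT controls from -1.31 to 0.65. The lowest values of MCINXTMP_009203 in flown PT butterflies were 4.05 CPM (female 4), 6.82 (male 1), 9.2 (female 7), 10.8 (female 2) and 18.7 (female 1). PT male control 2 had the highest values of the PT controls, with 35 CPM of MCINXTMP_003386, 94.3 CPM of MCINXTMP_009203 and a score of 0.65. The labels were used as given, and whether each of these butterflies flew, or carries the right label, is in doubt and was not tested. Any error there changes what these values mean: the 25 genes at 1 h, the 0 in PT alone (edgeR; 362 at an unadjusted p under 0.05), the 45 without PT male control 2, the 50 between times, and the 0 for the population difference at 1 h (edgeR; 369 at an unadjusted p under 0.05; DESeq2 0, limma voom 0). The same holds for the scores at 1 h that use PT butterflies. No count was made without these butterflies, since that would choose samples by their outcome.

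A hypothesis was that AL and PT share a flight response that gene-by-gene correlations miss. In each population alone, up to 50 genes per direction with the smallest p were chosen (those also among the 7643 genes were used), and the mean log2 CPM of the higher minus the lower set, with the mean of each sex subtracted, was scored in the other population, in 6 tests with those across times. At 1 h, genes chosen in PT gave AL butterflies a score 0.49 higher on average after flight, above the control median in 13 of 13 (exact permutation p = 0.000885, adjusted p = 0.00531). The ranges overlapped (flown -0.151 to 0.963, controls -0.649 to -0.065), the difference was 0.72 in females and 0.1 in males (2 male controls), and with labels permuted within sex it stood closer to the threshold (permutation p = 0.0045, adjusted p = 0.045 over 10 tests). Genes chosen in AL gave 0.93 in PT, above the control median in 12 of 16 (exact permutation p = 0.0281, adjusted p = 0.0843), which missed the threshold. At 20 h the differences were 0.48 from AL to PT (9 of 15, exact permutation p = 0.177, adjusted p = 0.265) and 0.31 from PT to AL (12 of 15, exact permutation p = 0.161, adjusted p = 0.265). These values suggest a shared response at 1 h in 1 direction of the test and leave it open at 20 h. Genes chosen at 1 h gave 0.23 at 20 h (25 of 30, permutation p = 0.242, adjusted p = 0.29) and genes chosen at 20 h gave 0.12 at 1 h (19 of 29, permutation p = 0.633, adjusted p = 0.633), so a response shared between the times stays open. Within population and sex, genes chosen at 1 h gave 0.62 at 20 h in AL (permutation p = 0.0295, adjusted p = 0.106) and -0.09 in PT (permutation p = 0.78, adjusted p = 0.863), and genes chosen at 20 h gave 0.34 at 1 h in AL (permutation p = 0.155, adjusted p = 0.327) and -0.06 in PT (permutation p = 0.863, adjusted p = 0.863). The signs of the latter differed by sex: 0.75 in females and -0.35 in males of AL, and 0.24 and -0.5 in PT. Differences between populations or sexes in these scores were not tested.

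Another hypothesis was that called genes sit beside each other in the numbering of the gene models, tested by counting pairs of consecutive numbers against 10000 shuffles within 10 classes of mean expression, over 7 sets. Genes higher in females formed 72 pairs against a shuffled mean of 44 (p = 0.0001, the smallest the shuffles can give, adjusted p = 0.0007), and genes higher in AL 269 against 226.2 (p = 0.001, adjusted p = 0.0035). Genes higher after flight at 20 h formed 3 pairs against 0.5 (p = 0.02, adjusted p = 0.047). The adjustment used rounded p-values, so whether this set passes the threshold is not settled. Genes higher in males formed 50 pairs against 38.9 (adjusted p = 0.07) and genes higher in PT 181 against 168.8 (adjusted p = 0.28), which missed the threshold. Shuffles without the expression classes, run first, gave p = 0.006 for males and 0.03 for PT. Genes higher at 1 h and lower at 20 h after flight formed 0 and 0. The 5 genes lower after flight at 1 h were not among the sets tested, though they include the consecutive MCINXTMP_011855 and MCINXTMP_011856. Such pairs, whether among these or the female and AL genes, may come from neighbouring copies or from gene models that split the same gene. They may also come from reads shared between copies. These sources cannot be separated without sequences or positions.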
